A study of Homo sapiens with 2 samples.

How the data were processed

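Total RNA from parental MIA PaCa-2 cells and from a radiation-resistant subline of MIA PaCa-2 was measured on 2 microarrays, 1 per group. MIA PaCa-2 is an established cell line from a human pancreatic ductal carcinoma. Per the labels' protocols, pancreatic cancer lines were irradiated with 2 Gy at each passage until the summed dose reached at least 60 Gy, and RNA was amplified to Cy3-labelled cRNA. No replicate array was analysed here, so no difference has a replicate error, and no test or p-value was computed for any of them.

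Per the file headers and the submitters' processing notes, each 1-colour array was scanned and quantified with Agilent Feature Extraction 12.0.3.1, whose processed signal is a background-subtracted and detrended spot intensity. The processed intensity had no scaling between the arrays, per the file headers. The mean and local background intensity of each spot and the flags for spots well above background, outlying or saturated also came from the deposited scanner files. The authors' deposited value table held a linear ratio, the processed intensity of each feature over 1 constant per array. That constant was 292.2 for the parental array and 245.0 for the radiation-resistant array, close to the arrays' 75th percentiles over all features (292.2 and 245.0). The table's scale was therefore linear, its genes were not centred, and its columns had medians of 0.0412 and 0.0466. The table was used as an alternative only.

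The main value was log2 of the processed signal minus log2 of the array's 75th percentile over its 60901 non-control spots. Control spots and spots flagged as outliers were left out, and repeated spots of a probe were averaged. Of 58201 probes, 33875 received a gene symbol through the RefSeq table of assembly GRCh38.p14, by accession for 30532, by symbol for 2847 and by older symbol for 496. The other 24326 probes had no symbol there. Probe positions are those of the scanner files, on hg19. A gene was represented by its probe with the highest mean level among probes well above background on at least 1 array, which gave 15331 of 22762 genes. Of these, 14313 were measured on both arrays, 468 were well above background only in the radiation-resistant array and 545 only in the parental array. In 5 genes the arrays were above background with different probes. For a gene above background on 1 array, the difference is a lower bound against the higher of the dim array's lowest signal well above background and the dim probe's own signal.

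Differences are log2 levels of the radiation-resistant minus the parental array. Genes were counted as higher or lower by size alone, at 2-fold. For 33 gene lists, the median difference of the measured members, with signals below an array's floor set to it, was placed among 10000 random lists of the same size matched on mean level in 20 bins. A list was said to stand apart below the 1st or above the 99th percentile, as a description of these arrays. With 33 lists, 0.66 would lie outside if list members varied independently, as in the random draws. Members of a list may vary together and some lists share members, so this is not a chance rate for these lists. Windows of 50 neighbouring genes were compared with 1000 shuffles of gene order. The list members, the size threshold and the rule for naming genes were set before the data were examined. The rule named CXCR4, CXCL12 and ACKR3, the 12 largest differences in each direction, the 5 largest bounds in each direction, and up to 4 members of each list measured on both arrays at least 2-fold apart, or the 2 most different where none was. The 12 largest differences were taken among genes measured on both arrays whose probes agreed in sign. Y-linked genes were not named. The value of 1 gene that the rule names is not reported here. Other members named below (among them DUSP6, MMP3, CCN2, FAS, ESRP1, HSP90AA1, SPARC and COL3A1) were chosen after their values were seen.

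Measurement error came from 300 probes printed as 10 spots each. Over the 272 of them above background on both arrays, the SD of log2 signal within a probe was 0.07 on either array, and the SD of a difference between single spots was 0.09. It was 0.15 in the dimmest 20% of these probes. This error covers the spot alone, not the culture, the RNA or the labelling. For arrays, their number limits the precision.

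Alternatives were normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), quantile scaling, scaling to the median of probes above background, no scaling, the authors' value table, the mean over a gene's probes, outlier spots kept, no filter and a stricter filter on dim probes (4 times the floor), list members on both arrays only, thresholds of 1.5-fold and 3-fold, all features with or without a symbol, and windows of 25 and 100 genes. Scaling to the E1A spike-in probes and a correction for probe GC content were added after seeing the data. All other steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

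The steps were tested on simulated data for the same comparison, with the real gene levels, a spot SD of 0.1 and 200 shifted genes among 14313. Genes shifted by 1.5 on the log2 scale were found at least 2-fold apart in 100% of cases, genes shifted by 0.5 in 0%, and unshifted genes in 0%. The simulated noise was that of spots alone, below the SD of 0.47 between the differences of 2 probes of a gene. These percentages therefore check the steps and give no error rate for the real counts. A list shifted by 0.5 lay at the 100th percentile, and 1% of 100 unshifted lists lay outside the 1st to 99th percentile. These list values also only check the steps and give no error rate for real lists. Real gene differences had an SD of 0.69, above the simulated noise, and members of the unshifted lists varied independently.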

Results

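Gene expression was measured in parental MIA PaCa-2 pancreatic cancer cells (1 array) and in a radiation-resistant MIA PaCa-2 subline (1 array). The series concerns the chemokine CXCL12 and its receptor CXCR4 in radiation-resistant pancreatic cancer, and the comparison asks how transcript levels differ between the subline and its parental line. Both arrays carried 62976 features, none of the non-control spots was saturated, and 48.4% of spots in the parental and 48.0% in the radiation-resistant array were well above background. The 75th percentile of processed signal was 311.3 in the parental and 260.8 in the radiation-resistant array. Levels of the 14313 genes measured on both arrays correlated across genes with Pearson's r = 0.974, genes not being independent replicates. There are no replicates, so each difference below describes these arrays, with a spot error of 0.09 (SD of a log2 difference of single spots).

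At 2-fold, 897 genes were higher and 688 were lower in the radiation-resistant array among the 14313 genes measured on both. A further 183 genes were well above background only in the radiation-resistant array, and 144 only in the parental array, by at least 2-fold. With normexp background correction these counts were 444 higher, 508 lower, 26 and 44. At 1.5-fold 2039 genes were higher and 2192 lower. Sizes and the balance of directions thus depended on the background correction and the threshold. The normexp setting added an offset of 50 to every signal, which by construction shrinks the differences of dim genes. The balance also depended on the scaling: 56.6% of the genes at least 2-fold apart were higher with the 75th percentile, 28.3% with no scaling and 81.0% with spike-in scaling, for which the median of all genes was −0.06, −0.31 and 0.21. These 3 scalings shift the medians of all gene lists alike and leave their percentiles as they are. Where 2 probes of a gene were above background on both arrays (4231 genes), the second probe had the same sign in 341 of 366 genes that differed at least 2-fold by the brightest, and was itself at least 2-fold apart the same way in 211 of them. The SD between the differences of the 2 probes was 0.47, larger than the spot error.

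The largest difference among genes measured on both arrays whose probes agreed in sign was in MMP1, the interstitial collagenase (probe on chromosome 11, 102660697 to 102660756). Its log2 level was 4.45 in the parental and −1.92 in the radiation-resistant array, 83.1-fold lower. NR5A2, a nuclear receptor of pancreatic and liver cells, was 48.8-fold lower. Its log2 level of −4.03 in the radiation-resistant array was close to that array's lowest signal well above background (−4.32). The aldo-keto reductases AKR1C1 and AKR1C8 were 38.1-fold and 25.5-fold lower. PSG8 (−5.22), a pregnancy-specific glycoprotein, ISOC1 (−4.94), MYBPH (−4.87) and the zinc and manganese transporter SLC39A8 (−4.48) were also lower on the log2 scale. PLAAT1 (−4.46), the endotoxin co-receptor CD14 (−4.38), ROR1-AS1 (−4.25) and WLS (−4.25), which carries WNT proteins to the cell surface, completed the 12 genes named for the most reduced levels. Another AKR1C1 probe gave −3.84 and another WLS probe −2.27. AKR1C and PSG probes lie in families of similar sequence, so signal may be shared between family members.

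In the other direction, CDA, the cytidine deaminase that inactivates gemcitabine, was 34.5-fold higher in the radiation-resistant array (probe on chromosome 1, 20945069 to 20945128), with log2 levels of −2.66 and 2.45. The stress-response protein NUPR1 was 32.5-fold higher and reached a log2 level of 6.15. PRICKLE1, of the planar polarity pathway, was 28.5-fold higher, the growth factor IGF2 was 21.5-fold higher, and the Notch ligand JAG1 was 15.4-fold higher. ADD3 (4.08), PRODH (3.75) and TNFSF10 (3.67), which encodes the death ligand TRAIL, were also higher on the log2 scale. ANXA10 (3.64), TRPV2 (3.61), FBXO27 (3.56) and SNAP25 (3.51) completed the 12 genes named for the largest differences in this direction. The probes of PRODH differed in size, from 0.57 to 3.75.

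Some genes were above background on 1 array only. TNFSF4, the OX40 ligand, was at least 247-fold lower in the radiation-resistant array, CARD16 at least 219-fold, the metallothionein MT1G at least 84.8-fold, CARD17P at least 68.4-fold and TRIML2 at least 49.0-fold. Only in the radiation-resistant array, DCDC2 was at least 57.6-fold higher, the transcription factor IKZF2 at least 45.2-fold, CD302 at least 21.8-fold, ATP4A at least 21.3-fold and PASD1 at least 17.7-fold.

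**Figure D1:**
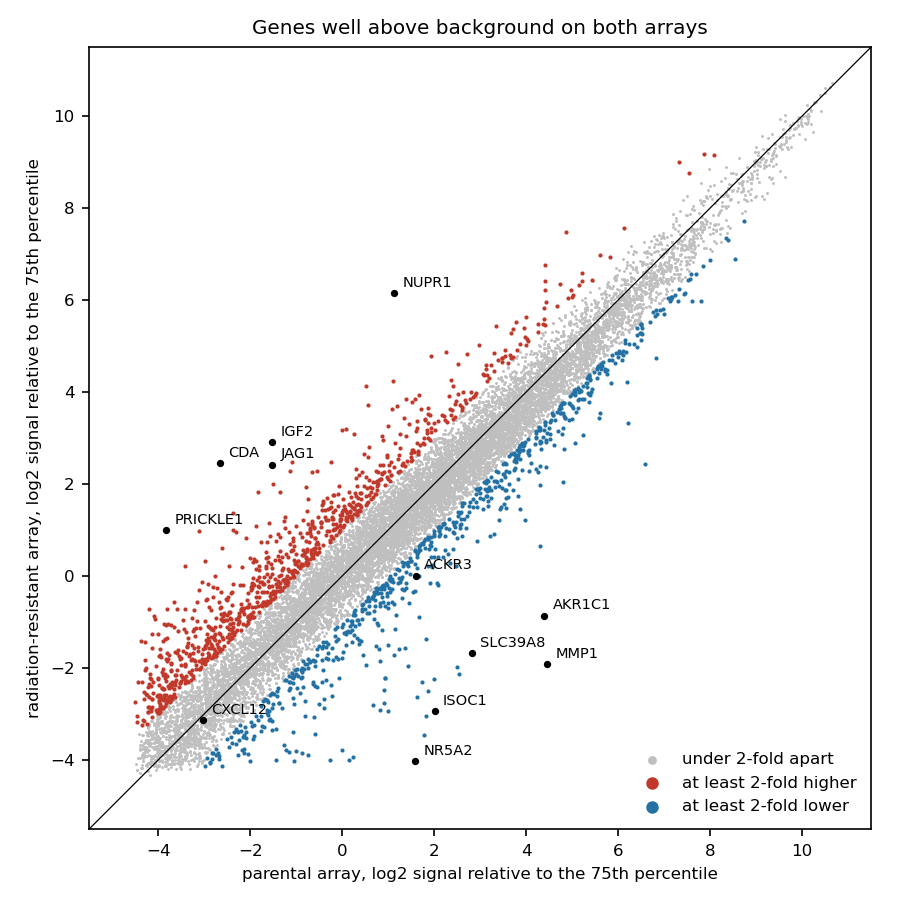
Log2 level relative to the 75th percentile in the parental array (horizontal) and in the radiation-resistant array (vertical), 1 point per gene measured on both, with the line of equal levels. The 897 genes at least 2-fold higher lie above the line and the 688 at least 2-fold lower lie below it. Of the named genes shown, MMP1 (−6.38) and CDA (5.11) lie farthest from the line in each direction.

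CXCR4, the receptor of CXCL12, was well above background in the radiation-resistant array and not in the parental array. Its probe (chromosome 2, 136871953 to 136872012) was printed as 10 spots, of which 9 were free of outlier flags on both arrays. The mean log2 signal was −5.64 ± 0.80 (SD over 9 spots of 1 array) in the parental and −2.70 ± 0.10 (SD over 9 spots of 1 array) in the radiation-resistant array. All 9 spots were above background in the latter and 0 in the former. CXCR4 was thus at least 3.54-fold higher, a log2 bound of 1.82. With normexp background correction the bound was 0.66, below the 2-fold threshold.

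The ligand gene CXCL12 was dim on both arrays, at levels close to that of CXCR4 in the radiation-resistant array (log2 level −2.70). Of its 4 probes, 1 was well above background (chromosome 10, 44880394 to 44880453), with log2 levels of −3.02 in the parental and −3.13 in the radiation-resistant array, and the other 3 were not. The alternative CXCL12 receptor ACKR3 (chromosome 2, 237490783 to 237490842) was 3.01-fold lower, from 1.60 to 0.01. Among 46 chemokine and chemokine receptor genes, 15 were measured. CCR10 was higher by 1.19 and CXCL1 had a difference of −1.01 (−0.71 by another probe). The list's median of 0.05 lay at percentile 58.7 of matched lists.

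**Figure D2:**
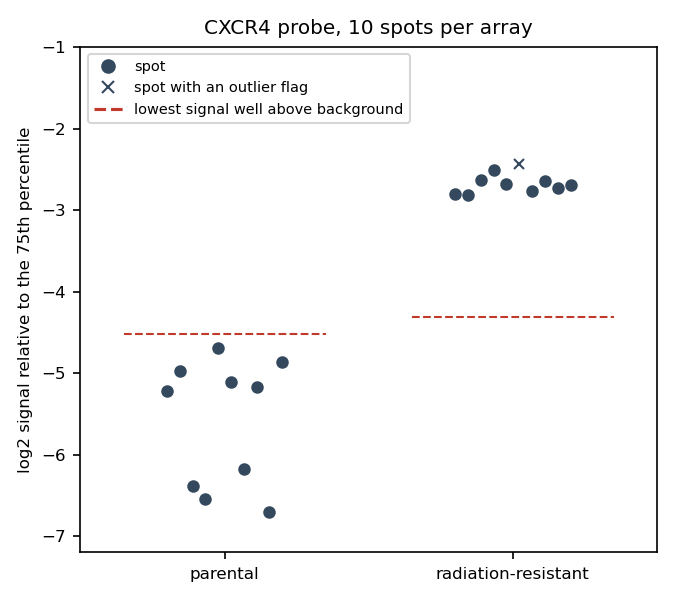
Log2 signal relative to the 75th percentile of each of the 10 CXCR4 spots on either array, with the lowest signal well above background of each array as a dashed line and a cross for a spot with an outlier flag. The parental spots lie between −6.71 and −4.69, below their line, and the radiation-resistant spots without a flag between −2.82 and −2.51, above theirs.

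Genes of the cell cycle were lower as groups in the radiation-resistant array, under every scaling tried. All 34 measured genes of G1/S and DNA replication were lower, 28 of them at least 2-fold, with a median of −1.29. Examples were the cyclin CCNE2 (−2.45), the transcription factor E2F2 (−1.88) and UHRF1 (−1.77), which maintains DNA methylation. The ribonucleotide reductase subunit RRM2 was at −2.25 by its brightest probe, but another probe gave 1.57. All 30 genes of G2/M and mitosis were lower, 14 of them at least 2-fold, with a median of −0.94. They included the proliferation marker MKI67 (−1.41), KIF23 (−1.34), the kinase AURKA (−1.21) and HMMR (−1.20). All 18 measured replication-dependent histone genes were lower, 16 of them at least 2-fold, with a median of −1.37, as in H1-2 (−1.99), H1-5 (−1.88), H2BC12 (−1.58) and H2BC5 (−1.55). Each of the 3 medians was lower than in all of the 10000 matched random lists.

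Most measured DNA repair genes were lower with the 75th percentile, 26 of 29, 20 of 24 and 15 of 20 in the 3 lists below, and differences between these lists were not tested. Of 29 homologous recombination and Fanconi anaemia genes, 11 were at least 2-fold lower and 0 higher, and the median of −0.66 lay at percentile 0. Matching was on level alone, so whether lower repair genes are separate from the lower cell cycle genes was not tested. EXO1 was at −1.82, XRCC2 at −1.66 and BRCA2 at −1.32. The lists of end joining and damage sensing (24 genes, median −0.33, percentile 2.49) and of base excision repair (20 genes, median −0.32, percentile 7.04) did not stand apart, and with spike-in scaling their medians were −0.06 and −0.05. In the former, the polymerase POLQ (−1.28) and the histone H2AX (−1.14) were at least 2-fold lower. In the latter, FEN1 (−1.68) and NEIL3 (−1.35) were lower and NEIL1 (1.22) was higher.

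Interferon-stimulated genes were higher in the radiation-resistant array. Of 32 measured type I interferon response genes, 17 were at least 2-fold higher and 0 at least 2-fold lower, and the median of 1.04 exceeded all matched random lists. IRF9, the DNA-binding subunit of the interferon-activated complex ISGF3, was higher by 2.43, although its probes ranged from 0.77. IFI27 was higher by 2.13, BST2 (tetherin) by 2.02 and MX1 by 1.83. Class I antigen presentation genes had a median of 0.37 at percentile 99.9, with 2 of 18 genes at least 2-fold higher, the immunoproteasome subunit PSMB8 (1.06) and the aminopeptidase ERAP2 (1.03), and 6 of 18 lower. Without scaling this median was 0.11. The list of NF-kB targets and inflammatory cytokines did not stand apart (percentile 75.7). Its median was 0.00 and its mean −0.60, with 4 of 19 genes at least 2-fold lower, namely NFKBIA (−1.24), CXCL1 (−1.01), MMP1 (−6.38) and MMP3 (bound −5.02). Another CXCL1 probe gave −0.71, under 2-fold.

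Stress-response groups also stood apart. The unfolded protein and integrated stress response list had a median of 0.41 at percentile 100, with 5 of 25 genes at least 2-fold higher. These included ATF3 (2.54), the glutathione-degrading enzyme CHAC1 (2.11), DDIT3, which encodes CHOP (1.37), and PPP1R15A (1.20). Another ATF3 probe gave −0.23. The immediate early and heat shock list had a median of 0.35 at percentile 100, with 8 of 20 genes at least 2-fold higher. This list shares ATF3 with the previous one. FOSB (2.20), FOS (1.60) and EGR2 (1.55) were also higher, whereas the chaperone HSP90AA1 was at −0.82. The medians of these 2 lists were 0.26 and 0.18 with the correction for probe GC content and 0.15 and 0.10 with no scaling. Hypoxia and glycolysis genes had a median of 0.16 at percentile 99.01, which became −0.10 with no scaling. NDRG1 (2.02) and DDIT4 (1.74) were higher. MXI1 was 2.83-fold higher and PDK1 was higher by 1.42. This list did not stand apart with quantile scaling (percentile 98.3) or with outlier spots kept (percentile 98.8).

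The epithelial list stood apart at percentile 99.7 with a median of 0.44. Of its 21 measured genes, 5 were at least 2-fold higher and 3 at least 2-fold lower. The mucin MUC1 was higher by 3.12 and the transcription factor ELF3 by 2.12, while the claudins CLDN1 (−1.68) and CLDN4 (−1.40) were lower. ESRP1, an epithelial splicing factor, was above background in the parental array only (bound −2.36). Mesenchymal and extracellular matrix genes had a median of 0.01 at percentile 79.3 and went both ways. TGFB1 was higher by 2.73, TGFBI by 2.26 and TAGLN by 1.36, whereas CCN1 was at −1.43 and CCN2 at a bound of −2.69. Integrins and matrix metalloproteinases had a median of 0.34 at percentile 99.3 and a mean of −0.15, with MMP1 (−6.38) and MMP3 (bound −5.02) far lower. ITGB4, the laminin-binding hemidesmosome integrin, was higher by 2.36 and ITGA10 by 1.17. This list's percentile was 98.7 with normexp, 97.8 with the mean over probes, 97.0 without a filter on dim probes and 98.0 with the correction for probe GC content. The neuroendocrine list rested on 5 measured genes, of which SNAP25 was at least 2-fold higher. Its median of 0.86 lay at percentile 99.5, but at percentile 98.3 with normexp and at percentile 28.2 without a filter on dim probes. The neuroendocrine list did not stand apart with the correction for probe GC content either.

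Antioxidant targets of NRF2 had a median of −0.35 and lay at percentile 2.06, with 5 of 25 genes at least 2-fold lower and 0 higher. AKR1C1 (−5.25), AKR1C3 (−3.39) and the aldose reductase AKR1B1 (−2.22) had the largest differences, followed by the thioredoxin reductase TXNRD1 (−1.26). With normexp or quantile scaling this list lay below the 1st percentile, at 0.57 and 0.76.

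Of the 27 measured p53 target genes, 3 were at least 2-fold higher and 3 lower, with a median of 0.05, a mean of −0.09 and percentile 83.9. PHLDA3 (1.70), TP53INP1 (1.34) and BBC3 (1.31), which encodes PUMA, were higher. PMAIP1, which encodes NOXA, was at −3.15 and FAS at a bound of −2.77. Members of the BCL2 family, IAPs and caspases went both ways (median −0.07, percentile 59.4), with BMF (2.84) and HRK (1.19) higher and BCL2 (−1.16) and CYCS (−1.05) lower.

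The other lists stayed inside the range of matched lists. MAPK feedback and target genes had a median of 0.15, a mean of −0.17 and percentile 94.7. Within them EPHA2 was at −0.94, SPRY1 at 0.82 and DUSP6, a phosphatase of ERK, at a bound of −5.53. WNT target genes had a median of −0.10 (percentile 35.9), with BAMBI at −1.42 and TCF7 at 1.16. Stemness-associated genes had a median of −0.11 (percentile 40.9), with NANOG at −1.62 and KLF4 at −1.33. Cholesterol genes had a median of −0.16 (percentile 55.4), with TM7SF2 at 1.04. Drug transporters of the ABC family had a median of 0.12 (percentile 72.5), with ABCA2 at 1.20. Cancer/testis antigens had a median of −0.23 (percentile 15.8), with PRAME at 0.58 and MAGEA6 at −0.51. Metallothioneins had a median of −0.14 (percentile 51.8) and a mean of −1.14, with MT3 at 0.38 and MT1X at −0.34. Of these 10 genes, 2 were at least 2-fold lower, MT1G (bound −6.41) and MT1F (bound −3.77). Ribosomal protein genes had a median of −0.14 (percentile 86.6) and respiratory chain genes one of −0.21 (percentile 58.8), and none of their members was 2-fold apart, the most different being RPL8 (0.39), RPL35 (−0.35), NDUFA2 (−0.80) and ATP5MC1 (−0.69).

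Markers of other cell types did not stand apart. Fibroblast markers had a median of 0.43 at percentile 95.4, with COL6A2 (1.62) and COL1A2 (1.04) higher, and lay at percentile 99.1 without a filter on dim probes or with members on both arrays only, and at percentile 99.5 with the stricter filter. COL3A1, an abundant fibroblast collagen, was above background in the parental array only (bound −1.91). Leukocyte markers had a median of 0.48, a mean of −0.18 and percentile 93.7, with CD14 at −4.38. Endothelial markers (6 measured genes) had a median of −0.44 at percentile 6.01 and a mean of −1.01, with CDH5 at −0.70 and EGFL7 at 0.56. EMCN (bound −2.66) and ROBO4 (bound −3.08) were at least 2-fold lower. With the stricter filter the median of this list was 0.56 at percentile 93.4. Pancreas markers had a median of 0.02 at percentile 38.0, with INS at 0.30 and IAPP at 0.05. Of the 6 measured pancreas markers, 1 was at least 2-fold higher and 0 were at least 2-fold lower.

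**Figure D3:**
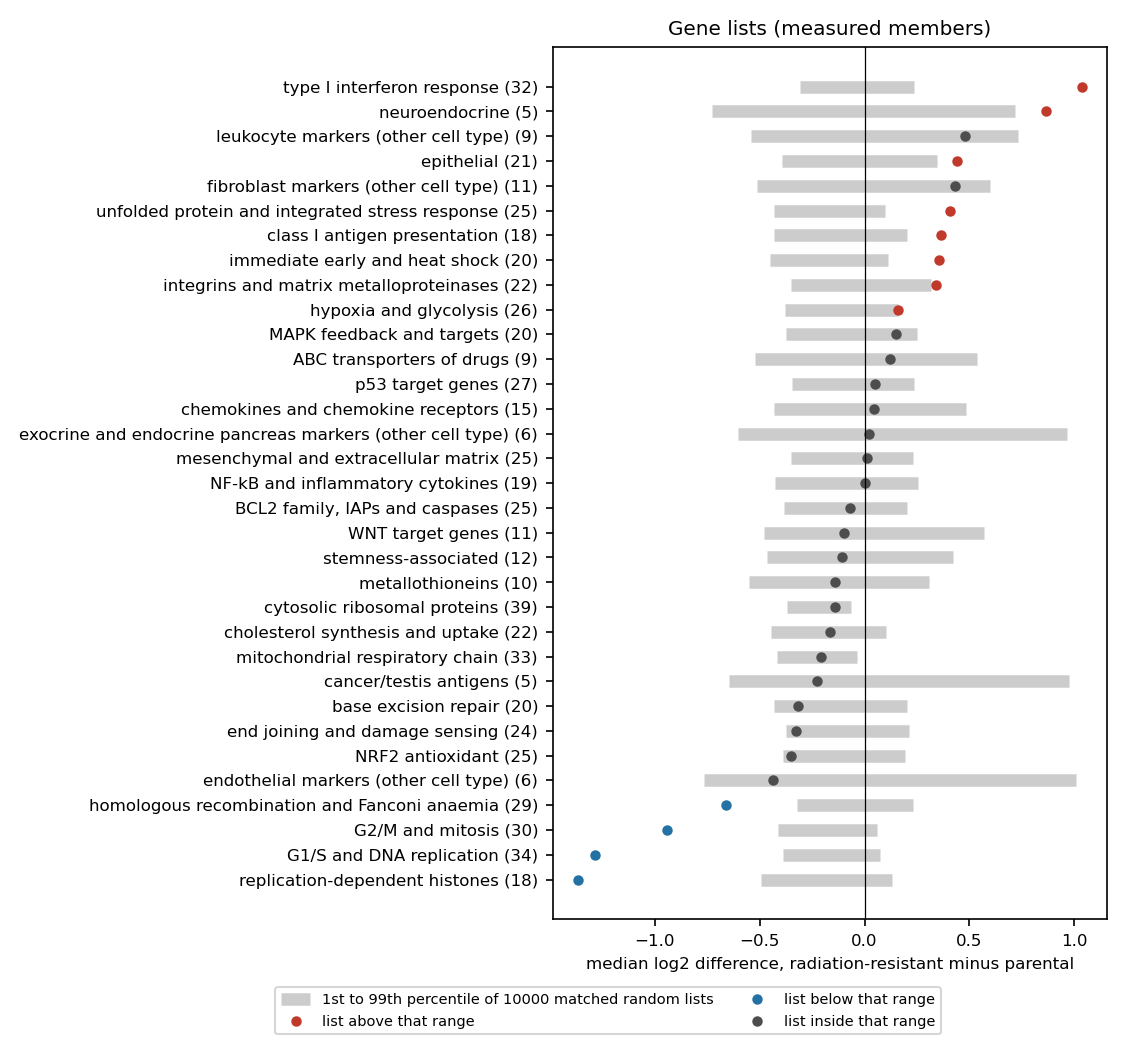
Median log2 difference (radiation-resistant minus parental) of each gene list, as a point, over the 1st to 99th percentile of medians of 10000 random lists matched on level, as a grey bar, with the number of measured members in brackets. The points of 8 lists lie above their bars, from hypoxia (0.16) to type I interferon (1.04), and those of 4 lie below, from homologous recombination (−0.66) to histones (−1.37).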

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

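The tests of explanations in this part were chosen after the results were seen, although the windows and quantile scaling themselves were planned, and they rest on 1 array per group. Among features without a gene symbol, which enter no comparison above, 218 were at least 2-fold higher in the radiation-resistant array than in the parental array and 201 at least 2-fold lower, out of 5613 measured on both.

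Genes of G1/S, G2/M and the replication-dependent histones were lower together. The arrays had a trend with probe GC content, from a median of −0.14 in the most AT-rich probes to 0.19 in the most GC-rich, but after it was subtracted the G1/S median was −1.21, and all 3 lists stayed below the 1st percentile. Brighter genes also had lower differences (−0.23 in the brightest 20% of genes, 0.14 in the dimmest 20%), yet with quantile scaling the G1/S median was −1.10. The random lists were matched on level and so carry this trend, and all 3 lists lay below the 1st percentile of them with either scaling. Quantile scaling therefore adds little to that comparison. Both trends are therefore argued against as the whole cause. A smaller share of dividing cells at harvest could also give lower levels of all 3 groups, as with the G2/M median of −0.94, and cannot be told apart from a lasting difference of the radiation-resistant subline, because the labels give no density at harvest and there is 1 array per group.

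Interferon genes were higher, and the class I antigen presentation list lay above matched lists by a smaller amount: its median was 0.37, or 0.11 without scaling, 2 of 18 genes were at least 2-fold higher and 6 of 18 were lower. The interferon median was 0.99 after the GC correction and 1.20 with quantile scaling, and in both settings the interferon and the class I list stayed above the 99th percentile, which argues against either trend as the whole cause. For the trend with level, the matched random lists already carry it, so quantile scaling adds little to the percentiles. Of 11 fibroblast markers, 8 were higher, among them COL1A2 (1.04) and COL6A2 (1.62), at percentile 95.4 (99.1 to 99.5 in 3 alternatives). RNA from fibroblasts would, however, bring all its abundant collagen and matrix transcripts. COL1A1 was near background in the radiation-resistant array (log2 level −4.09, bound 0.43), and COL3A1 and SPARC were above background in the parental array only, with bounds of −1.91 and −3.22. These levels argue against fibroblast RNA as the source. However, COL3A1 and SPARC were chosen after their values were seen, and the fixed list of fibroblast markers leans the other way. Fibroblast RNA is therefore not excluded, and the higher COL1A2 and COL6A2 have no tested explanation. The group itself, a subline irradiated repeatedly, remains an open and untested explanation, as do culture conditions that the labels do not give.

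Of 274 windows of 50 neighbouring genes, 5 had a median outside the shuffled range of −0.51 to 0.43. The count was 11 with quantile scaling and 9 with windows of 100 genes. The 5 windows lay on chromosome 5 from 205120 to 31401532 (−0.54) and from 126380474 to 135399402 (−0.52), on chromosome 6 from 26123983 to 27806513 (−1.13), and on chromosome 8 from 131307677 to 144780577 (0.47) and from 144789126 to 146203248 (0.64). Over all 607 measured genes of chromosome 5 the median was −0.32, the lowest of any chromosome, and −0.32 after the GC correction. The chromosome 8 window before these, from 105393414 to 131065549, had a median of 0.39, inside the shuffled range. After the GC correction the shuffled range was −0.44 to 0.48, and 4 of the 5 windows lay outside it. The first chromosome 8 window went from 0.47 to 0.44, inside the new range, and stays open. The second chromosome 5 window went from −0.52 to −0.48, inside the range before the correction, and stays open too. The other windows lay outside both ranges, which argues against the GC trend as their whole cause. In the chromosome 6 window, the 16 genes other than histones had a median of −0.0076 against −1.34 for its 34 histone genes, so the histone genes may account for that window. A different DNA copy number on chromosome 8 could shift neighbours together, and 94.0% of the genes in the last window were higher, but it cannot be told apart from other causes because no DNA was measured and the window was chosen for its shift.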

How the results depend on the processing

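Each result was recomputed under the alternatives listed with the methods, and spike-in scaling and the probe GC correction were chosen after seeing the data. Of 33 lists, 28 kept their side of the 1st and 99th percentiles in all 12 alternatives run for lists, 4 of which (no scaling, spike-in, median of probes, authors' table) shift all genes alike and could not move a percentile. Of 120 named genes other than CXCR4, 1 at least 2-fold apart changed sign in 1 of 9 alternatives: RRM2 was at 0.16 with the mean over its probes, which disagree. Among those less than 2-fold apart, CXCL12 changed sign with normexp (0.10) and spike-in scaling (0.15), and IAPP with no scaling (−0.20) and quantile scaling (−0.0043). Sizes were less stable than signs. Of the 120 genes, 81 moved by more than the spot error of 0.09 with normexp, 49 with the GC correction and 43 with quantile scaling. All 120 moved with no scaling or spike-in scaling, and 25 besides RRM2 with the mean over probes. In the other alternatives 0 moved. Except where its construction shows it, the cause of a shift below was not tested. Construction shows it for thresholds, filters, more features, and no scaling or spike-in scaling, which shift all genes alike. The normexp offset of 50 by construction shrinks the differences of dim genes, and its share in the normexp shifts was not tested. With normexp, 444 genes were higher and 508 lower, 26 and 44 were above background on 1 array only and at least 2-fold apart (higher and lower), the CXCR4 bound was 0.66, the spot spread 0.19, and the medians were −0.39 for NRF2, now apart, and 0.22 for integrins and 0.50 for neuroendocrine genes, no longer apart. With quantile scaling, the CXCR4 bound was 1.71, 11 windows lay outside, NRF2 (−0.26) stood apart and hypoxia (0.25) did not. With no scaling, 550 genes were higher and 1396 lower, and the CXCR4 bound was 1.57. With spike-in scaling these were 1470, 344 and 2.09. The 7 spike-in probes differed by a median of −0.52 before scaling, against −0.26 for the 75th percentiles. With the mean over probes integrins (0.24), with outlier spots kept hypoxia (0.16), and with the GC correction integrins (0.26) and neuroendocrine genes (0.72) no longer stood apart. Without a filter on dim probes, 2112 genes were higher and 1419 lower, integrins (0.20) no longer stood apart, neuroendocrine genes (0.18) went below the middle of matched lists, and fibroblast markers (0.28) stood apart, as they did with the stricter filter (0.60) and with members on both arrays only (0.56). At 1.5-fold, 2039 genes were higher and 2192 lower, with 348 and 236 that far apart on 1 array only. At 3-fold these were 315, 168 and, only in the radiation-resistant array, 85. With all features, 329 and 229 were on 1 array only and at least 2-fold apart. With windows of 100 genes, 9 lay outside. No paired analysis was possible because there is 1 array per group. Signal over background limits CXCR4 and the other genes above background on 1 array only, whose differences are bounds. Genes above background on both arrays have plain differences even close to the floor. IFI27 and BMF, for example, had parental log2 levels of −4.43 and −4.28 against a floor of −4.52.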

Other observations

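Neighbouring genes were looked at after the results were seen, in runs of 5 genes along each chromosome. Runs with a median outside the shuffled range of −3.70 to 3.49 were merged where they overlapped. This gave 2 merged runs that were lower and 0 that were higher. One held the inflammatory caspase cluster on chromosome 11, where the radiation-resistant array was lower for CASP4 (−2.88) and CASP5 (−2.75), and where CASP1 (bound −3.93), CARD16 (bound −7.78) and CARD17P (bound −6.10) were above background in the parental array only. GRIA4 (−0.43) and MSANTD4 (0.27), at its far end, were not 2-fold apart. Over all 7 genes of this merged run the median was −2.88, inside the shuffled range. The other held the pregnancy-specific glycoproteins on chromosome 19. All 8 measured PSG genes were at least 2-fold lower, 7 of them above background in the parental array only, with a median of −3.77. These genes are similar in sequence, and sharing of signal between their probes was not tested.

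The groups below were also chosen after the values were seen, and none was compared with matched lists. All 8 measured HOXA genes and all 9 HOXB genes were higher, 4 of the 8 and 5 of the 9 at least 2-fold, with medians of 0.93 and 1.07. Without scaling the medians were 0.68 and 0.81, and 6 of the 8 HOXA genes and all 9 HOXB genes remained above 0. HOXA7 was higher by 2.54 and HOXB6 by 1.54, while the 4 HOXC genes had a median of 0.02 (−0.24 without scaling), 1 of them at least 2-fold higher. Single genes of chromosome 11 picked for their values were IGF2 at 4.43, the cell cycle inhibitor CDKN1C at 2.51, SLC67A1 at 2.11, KCNQ1 at 1.73 and PHLDA2 at 1.62, which support no statement about a group. Of 10 genes of the mitochondrial genome, 8 were higher, with a median of 0.57. Without scaling the median was 0.32 and 7 were higher. ND5 was at 1.42, and ND6, the one encoded on the other strand, was at −1.78.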
